A study of Mus musculus with 4 samples.

How the data were processed

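Single-cell ATAC-seq was carried out on CD4 T cells of a T cell receptor transgenic mouse line, HV1, whose receptor recognises a B cell leukemia. In this assay the Tn5 transposase cuts accessible DNA in isolated nuclei, and droplets tag the resulting fragments with a barcode for each nucleus. The naive library held HV1 cells sorted from unchallenged transgenic mice. The other libraries held HV1 cells that had been transferred into CD45.1+ recipients, which were challenged with LM138 leukemia cells on the following day, and sorted at day 9, 13 or 17 after challenge. Each group was 1 library, and no number of mice per library is given in the sources used here.

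Each deposited file lists counts per barcode, with no normalization: read pairs by mapping outcome, unique fragments that passed the filters, and fragments or cut sites overlapping transcription start site (TSS) regions and peaks, per the file headers. Cell Ranger ATAC 2.1.0, Seurat 4, Signac and the mm10 mouse build are named in the submitters' processing notes, without settings. Which steps Seurat and Signac were used for, the width of a TSS region, and whether peaks were called separately for each library are not given in the sources used here. The cell call and exclusion code of each barcode were used as given in the files and were not recomputed. In all 4 libraries the 7 mapping outcomes added up to the total at every barcode. The on-target count equalled the TSS count at every barcode and was not used. The DNase-sensitive, enhancer, promoter and blacklist columns held 0 at every barcode, so they carried no measurement and these 4 region classes were not analysed. Gene-level and peak-level counts were not analysed here, so no gene is named; the items named are the 2 region classes with values (TSS regions and peaks) and mitochondrial DNA, by a rule fixed before the data were examined, as were the main measures and all alternatives except those identified as later additions.

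From these counts the following were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The TSS share and the peak share are fragments overlapping those regions over unique fragments, summed over called cells. The mitochondrial share is mitochondrial read pairs over all read pairs of called cells. Intervals are exact binomial 95% intervals and cover counting error only; fragments of 1 library are not independent replicates of a condition. With 1 library per group there was no test between groups, and neither cells nor fragments were treated as replicates. The number of unique fragments per cell at saturation was estimated by solving the Lander-Waterman equation for each cell from its unique and duplicate counts. On simulated cells with the real read depths, the median saturation estimate erred by at most 0.0371% over the 4 libraries. The thinned share erred by at most 0.0905 percentage points. The simulation followed the model that the estimate assumes, with every fragment of a cell equally likely to be read. These errors therefore check the calculation, and not whether real libraries follow that model.

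Libraries held 199167117 to 253255535 read pairs, of which 5.12% to 5.58% had no barcode. These were left out, and the main values used called cells only. Uncalled barcodes, with or without an exclusion code, were planned as a measure of background. They also entered 1 alternative cell count, that of barcodes with 1000 or more fragments. Exclusion codes were set at 100878 barcodes under code 3, 224962 under code 2 and 211 under code 1 over all libraries, and no called cell had one. Code 2 barcodes held 0% to 1.55% of their fragments in peaks, code 3 barcodes 63.9% to 77.5%, and code 1 barcodes 58.1% to 77.3%. The files do not define the codes. Of the fragments at uncalled barcodes, code 3 barcodes held 2238442 of 6508956 in the naive library and 1515161 of 5806468 at day 9. They held 4753248 of 9635990 at day 13 and 1567342 of 5324102 at day 17. Values at uncalled barcodes may therefore not be of background alone. No doublet caller was run.

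The alternatives were the median over cells, cells with 3000 or more fragments, cells with 5000 to 20000 fragments, thinning of every cell to 1000 fragments, leaving out the deepest 5% of cells, other depth measures and other cell filters. A filter on peak fragments (3000 to 20000), peak share (15% or more) and blacklist share (under 5%) was also tried for the cell counts; its blacklist part removed nothing because that column holds 0. A restriction to called cells with under 20% of read pairs unmapped was added after the data were examined, because the naive library held many barcodes whose read pairs did not map to the mouse genome.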

Results

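Chromatin accessibility was profiled in single nuclei of leukemia-specific HV1 CD4 T cells, from naive transgenic mice and from leukemic recipients at days 9, 13 and 17 after challenge, with 1 library at each. The naive library had 6734 called cells, day 9 had 3611, day 13 had 9923 and day 17 had 9072. Called cells held 56038211 unique fragments in the naive library, 88025966 at day 9, 132074251 at day 13 and 141768153 at day 17. With this depth the binomial intervals on summed shares were narrow, but no difference between libraries has a replicate check.

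The naive library was mixed. Of its called cells, 1988 (29.5%, 95% interval 28.4 to 30.6) had over 80% of their read pairs unmapped to the mouse genome, and only 4066 (60.4%) had under 20% unmapped. Under 20% unmapped were 3597 of the called cells at day 9, 9921 at day 13 and 9062 at day 17. The naive barcodes over 80% unmapped carried a median of 537.5 unique fragments from 11253 read pairs, so each weighed little in sums over fragments and fully in medians over cells. Values without the barcodes above 20% unmapped, a restriction chosen after seeing the data, are given beside the differences from naive cells.

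**Figure D1:**
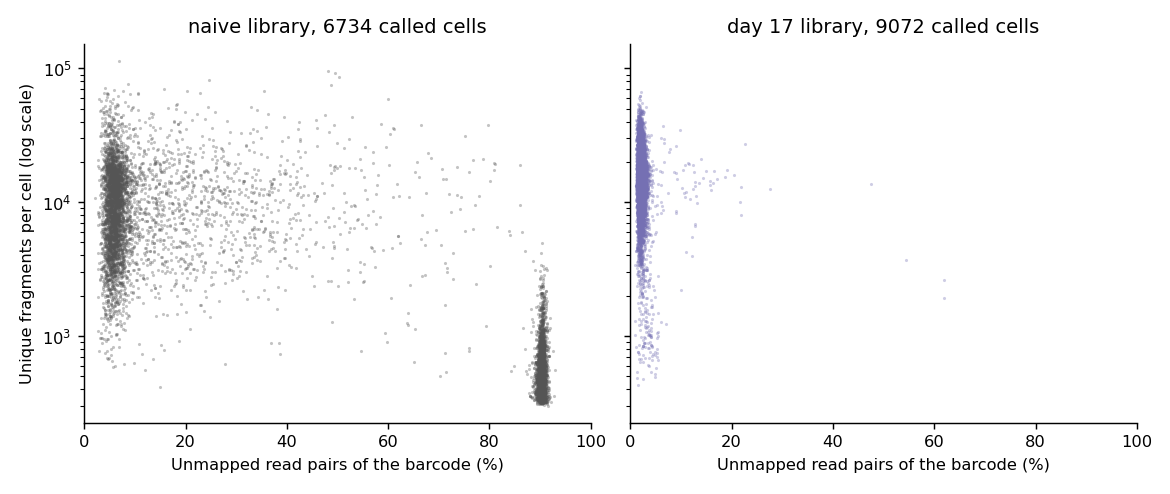
Unique fragments per called cell (vertical, log scale) against the percent of the barcode's read pairs that did not map (horizontal), 1 point per called cell, for the naive and day 17 libraries. The naive library has a separate cloud of 1988 barcodes over 80% unmapped, with a median of 537.5 fragments, while 9062 of the 9072 day 17 cells lie under 20%.

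The first comparison was of the share of fragments at TSS regions, where gene promoters lie. It set HV1 cells that had not met leukemia against HV1 cells recovered from leukemic mice. TSS regions took a larger share of fragments in all 3 leukemia libraries. The TSS share was 36.7% in naive cells (95% interval 36.71 to 36.74), 50.5% at day 9 (50.46 to 50.48), 51.5% at day 13 (51.48 to 51.50) and 53.8% at day 17 (53.82 to 53.83). Against naive cells, TSS regions held 13.7 percentage points more of the fragments at day 9, 14.8 more at day 13 and 17.1 more at day 17. Among called cells under 20% unmapped, the naive TSS share was 37.8% and the differences were 12.7, 13.7 and 16.0 percentage points.

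The TSS share of single cells moved as a whole distribution. The median cell had 36.5% of fragments at TSS regions in the naive library (38.3% under 20% unmapped), 51.4% at day 9, 52.5% at day 13 and 55.0% at day 17. Among cells under 20% unmapped, the quartiles of the TSS share were 36.4% and 40.03% in naive cells and 51.7% and 57.8% at day 17, so the interquartile ranges did not overlap. Within each library, cells under 20% unmapped with 1000 or more fragments spread more widely than counting allows: the standard deviation over cells was 3.49 percentage points in naive cells, where counting alone gives 0.599, and 5.06 at day 17, where it gives 0.450. Barcodes not called as cells included those with an exclusion code. Their TSS shares were 29.6% in the naive library, 47.3% at day 9, 50.0% at day 13 and 52.7% at day 17. In the naive library 77.3% of the read pairs at these barcodes were unmapped; among uncalled barcodes under 20% unmapped the TSS share was 41.2% in the naive library and 49.9%, 50.1% and 52.8% at days 9, 13 and 17.

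Between the leukemia libraries the TSS share differed less. Day 13 exceeded day 9 by 1.02 percentage points and day 17 exceeded day 13 by 2.33. The order of days 9 and 13 was reversed among cells with 5000 to 20000 fragments, where TSS regions held 52.7% of fragments at day 9 and 52.1% at day 13. Day 17 was highest in that window too, at 55.0%. The median day 9 cell had 21753 fragments, so the window left out most day 9 cells. With every cell thinned to 1000 fragments, the shares were 50.9% at day 9 and 51.9% at day 13.

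**Figure D2:**
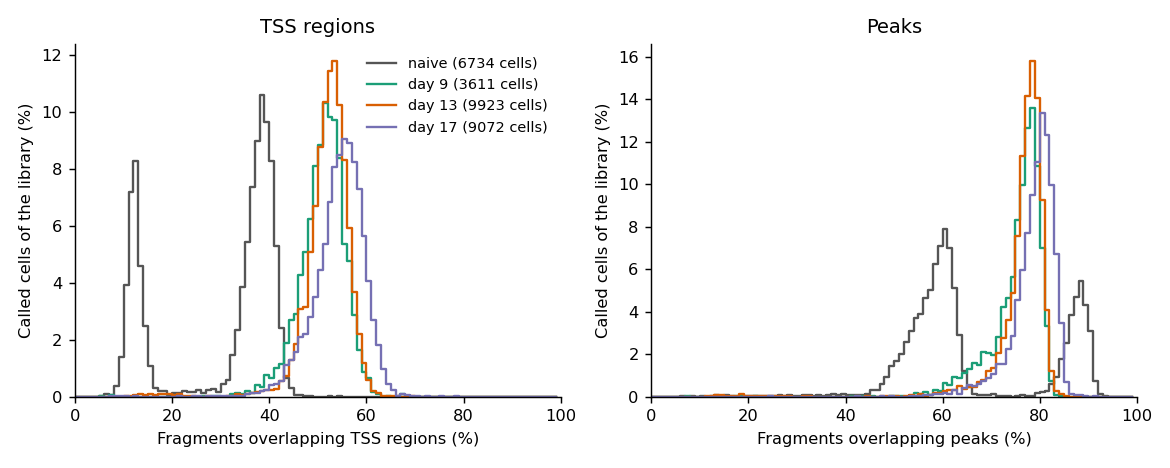
Distribution over called cells of the percent of a cell's unique fragments that overlap TSS regions (left) and peaks (right), in bins 1 percentage point wide, with the percent of the library's called cells on the vertical axis and 1 line per library. The naive library has its main TSS mode left of the 3 leukemia libraries (medians 36.5%, 51.4%, 52.5% and 55.0%), and a second mode at a low TSS share and a high peak share, where its barcodes over 80% unmapped lie.

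Peaks, the regions of concentrated accessibility found by the authors' pipeline, likewise took a larger share of fragments in the leukemia libraries. The peak share was 57.4% in naive cells (95% interval 57.40 to 57.43), 74.4% at day 9 (74.43 to 74.45), 75.6% at day 13 (75.59 to 75.61) and 78.2% at day 17 (78.20 to 78.21). The differences from naive cells were 17.0, 18.2 and 20.8 percentage points, and 17.6, 18.7 and 21.3 among cells under 20% unmapped. The TSS and peak shares were thus higher together, and whether TSS regions gained beyond peaks in general was not tested. Among peak fragments, both ends lay inside a peak for 85.2% in naive cells (84.4% under 20% unmapped), 95.1% at day 9, 95.6% at day 13 and 95.7% at day 17. Peak sets called separately would make these shares depend on which peaks each library yielded, and the naive barcodes over 80% unmapped held 84.9% of their mapped fragments in peaks but only 13.2% at TSS regions.

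Naive cells yielded fewer unique fragments than cells from leukemic mice. The median cell had 5573.5 fragments in the naive library, 21753 at day 9, 12298 at day 13 and 14565.5 at day 17, or 3.90, 2.21 and 2.61 times the naive value. Among cells under 20% unmapped the naive median was 9171, and these ratios fell to 2.37, 1.34 and 1.59. Day 9 cells were sequenced most deeply, at a median of 50235 read pairs per cell against 18353 at day 13 and 24055.5 at day 17, and 48.5% of their usable read pairs were duplicates. The saturation estimate adjusts for sequencing depth if every fragment of a cell is equally likely to be read. By that estimate the 3 leukemia libraries lay close together, at medians of 27433, 25278 and 25678 fragments per cell under 20% unmapped. Naive cells lay at 15993. At an equal median of usable read pairs per cell, the ratios to naive were 1.27, 1.26 and 1.26 over all called cells. They were 1.18, 1.16 and 1.16 under 20% unmapped. These ratios were computed from the saturation estimate at the naive median depth, 13758.5 usable read pairs under 20% unmapped. Each library's depths were scaled to the naive median, so cells within a library kept their relative spread of depth. A cell cannot give more fragments than usable read pairs, so the naive median of 9171 fragments limited how large these ratios could be.

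Cells from leukemic mice also differed in the evenness of recovery. The upper quartile of the saturation estimate was 2.68 times the lower quartile in naive cells under 20% unmapped, and 1.68, 1.51 and 1.49 times at days 9, 13 and 17. In the leukemia libraries the distribution had a shoulder above its main mode: 20.3% of cells at day 9 (95% interval 19.0 to 21.7), 16.0% at day 13 (15.3 to 16.8) and 14.7% at day 17 (14.0 to 15.4) had 1.5 to 3 times their library's median. The broader naive distribution placed 22.7% of cells (21.4 to 24.0) in the same range. The range of 1.5 to 3 times the median was not among the planned measures.

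**Figure D3:**
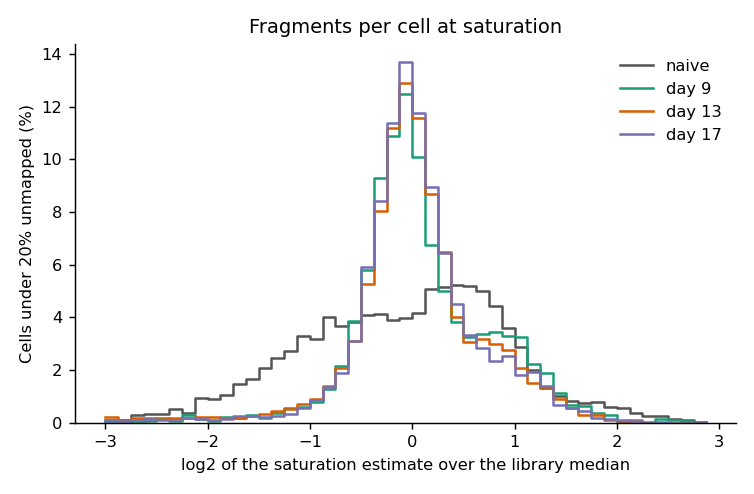
Distribution of the estimated number of unique fragments per cell at saturation, as log2 of its ratio to the library median (horizontal), with the percent of called cells under 20% unmapped on the vertical axis and 1 line per library. Days 9, 13 and 17 share a narrow main mode with a shoulder to the right, holding 20.3%, 16.0% and 14.7% of cells at 1.5 to 3 times the median, and the naive library is broader, with 22.7% in that range.

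Mitochondrial DNA, which is not packed into nucleosomes and is cut readily where mitochondria stay with the nuclei, did not follow the days in order. Its share of read pairs in called cells was 0.683% in the naive library (95% interval 0.682 to 0.684), 3.08% at day 9 (3.075 to 3.080), 0.463% at day 13 (0.462 to 0.464) and 1.80% at day 17 (1.794 to 1.798). Day 9 was thus 2.39 percentage points above naive cells, day 17 was 1.11 above, and day 13 differed by -0.22. Among cells under 20% unmapped, the naive share was 0.914% and the differences at days 9, 13 and 17 were 2.17, -0.451 and 0.883; over all alternatives the day 13 difference ranged from -0.587 to -0.175. Of mapped read pairs only, which leaves out the unmapped material, mitochondrial DNA made up 0.992% in called cells of the naive library, 3.17% at day 9, 0.472% at day 13 and 1.84% at day 17. At uncalled barcodes it made up 0.777%, 3.59%, 0.588% and 1.93% of mapped read pairs, in the same order.

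Day 13 stood apart in the spread of mitochondrial DNA over cells. Under 20% unmapped, 44.8% of its cells (95% interval 43.9 to 45.8) had under 0.03% mitochondrial read pairs, against 0.418% of naive cells, 0.0556% at day 9 and 2.15% at day 17. At the same time 16.4% of day 13 cells had 1% or more. These ends of the day 13 range were alike at TSS regions, with median TSS shares of 52.7% under 0.03% and 52.9% at 1% or more. The cutoffs of 0.03% and 1% were not among the planned measures. At a cutoff of 0.1%, also unplanned, 59.8% of day 13 cells lay below. The shares below 0.1% were 0.738% in naive cells, 0.195% at day 9 and 4.18% at day 17.

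**Figure D4:**
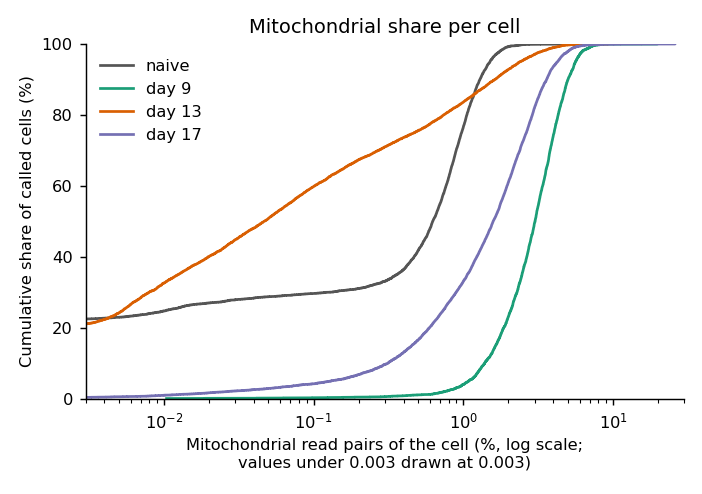
Cumulative percent of called cells (vertical) against the percent of a cell's read pairs that are mitochondrial (horizontal, log scale, values under 0.003 drawn at 0.003), 1 line per library. Day 9 cells are concentrated near their median of 3.02%. Day 13 cells are spread from under 0.003% to a maximum of 9.29%, with a median of 0.0468%. The low naive cells include the barcodes over 80% unmapped.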

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

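All tests in this part were chosen after the results they bear on were seen. The results here rest on unmapped read pairs, which the planned comparisons held only within totals, and on barcodes not called as cells, which were planned only as a background and within 1 alternative cell count.

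The naive library held 1988 called cells with over 80% of read pairs unmapped, against 1 at day 9 and 0 at days 13 and 17; since the naive library is itself the control, the comparison is with the leukemia libraries. Unreadable read pairs in mouse nuclei are argued against, because the fragments that did map held 13.2% at TSS regions, against 37.8% in naive cells under 20% unmapped. A separately captured library that entered through a shared or hopped sample index is argued against by the barcodes holding both kinds of material: 824 had at least 2000 unique fragments beyond those expected from their unmapped read pairs and at least 2000 unmapped read pairs beyond those expected from their mapped ones, 20.9 times the 39.4 that coincidence among 723080 barcodes gives. Nuclei or DNA of another organism in the same capture may be the source but stay open, since mouse mitochondrial read pairs made up 0.182% of mapped read pairs against 0.986% in cells under 20% unmapped, between the bounds set for and against, and the unmapped sequences were not analysed here. No biological explanation was tested.

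At day 9, 147 barcodes with 2000 or more read pairs were over 80% unmapped, 1 of them a called cell; 0 of the 147 were such barcodes in the naive library. They passed 4.95% of read pairs as unique fragments, close to the 4.85% of the 5322 such naive barcodes. Of these fragments, 18.0% at day 9 and 13.3% in the naive barcodes lay at TSS regions, and 24.0% and 83.9% lay in peaks. Peak sets called separately would make the peak shares depend on which peaks each library yielded. The peak shares therefore do not show whether the material differed between these libraries.

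Barcodes called as cells in 1 library carried more read pairs in each other library than barcodes called in none, by 0.0844% to 0.204% of their read pairs in the library of origin over the 12 ordered pairs of libraries.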

How the results depend on the processing

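Values of 3 are for days 9, 13 and 17 in that order. No difference from or ratio to naive cells changed direction. The order of days 9 and 13 reversed among cells with 5000 to 20000 fragments, in the TSS share (52.7% and 52.1%) and in the peak share (77.5% and 76.7%). That window left out most day 9 cells, whose median was 21753 fragments. Of 88 alternative values, 15 stayed within 1.5 times (cell counts) or within the interval of the main value and 73 moved beyond it. For ratios of medians the interval came from exact binomial limits on the ranks of both medians. For shares it covers counting error over all fragments or read pairs, such as 13.73 to 13.77 for the day 9 TSS difference. Nearly any change of setting moves a share beyond so narrow an interval, so the 73 do not measure how stable the results are. TSS share differences were 14.9, 16.0 and 18.4 percentage points by the median over cells, 13.2, 14.2 and 16.5 with 3000 or more fragments, 14.9, 14.3 and 17.2 with 5000 to 20000, 13.8, 14.9 and 17.3 without the deepest 5%, 14.7, 15.7 and 18.2 thinned to 1000 fragments (which left out 1772 naive, 5, 158 and 56 cells), and 12.7, 13.7 and 16.0 under 20% unmapped (added later). In the same order of settings, peak share differences were 16.3, 17.1 and 19.2; 17.7, 18.9 and 21.5; 20.1, 19.2 and 22.0; 16.6, 17.9 and 20.4; 16.6, 17.6 and 20.1; and 17.6, 18.7 and 21.3. Mitochondrial differences were -0.578 and 0.958 at days 13 and 17 by the median over cells, 2.36, -0.587 and 0.869 over mitochondrial, unique and duplicate read pairs, 2.23, -0.388 and 0.945 with 3000 or more fragments, 2.49, -0.175 and 1.20 without the deepest 5%, and 2.17, -0.451 and 0.883 under 20% unmapped. Ratios of fragments per cell were 2.69 and 2.47 at days 9 and 13 at saturation. They were 1.27, 1.26 and 1.26 at equal median usable read pairs, and 2.93, 1.60 and 1.88 by the mean. With 3000 or more fragments they were 2.17, 1.24 and 1.45, and for peak fragments 5.25, 2.98 and 3.65. Under 20% unmapped they were 2.37, 1.34 and 1.59, and 1.18, 1.16 and 1.16 with that restriction at equal median usable read pairs (added later). The naive cell count moved from 6734 to 4314 with 3000 or more fragments, 3329 under the peak filters and 4066 under 20% unmapped; the other 3 counts stayed within 1.5 times. Alternatives for the DNase-sensitive, enhancer, promoter and blacklist shares were not run, since those columns hold only 0. With 1 library per group, no library could be left out, and the spread between libraries of a group is unknown.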

Other observations

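The bounds of the tests on usable read pairs and duplicate share below were set before their results were seen, and day 17 was separated from days 9 and 13 afterwards; the window of 5000 to 20000 fragments was fixed before the data were examined, with its bound set after its result was seen, and the other tests were chosen after the results were seen.

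A small group of cells had few fragments at TSS regions or in peaks. Among cells under 20% unmapped, 96 at day 13 (0.968%, 95% interval 0.784 to 1.18) and 43 in the naive library (1.06%, 0.766 to 1.42) had under 25% of fragments at TSS regions, against 2 at day 9 and 5 at day 17. The day 13 cells had a median TSS share of 17.6% and peak share of 18.9%. Their medians of 12775 fragments and 0.0455% mitochondrial read pairs were near the 12300 and 0.0468% of all day 13 cells under 20% unmapped. The naive cells had a median TSS share of 18.5% and peak share of 25.9%. They had more fragments than all naive cells under 20% unmapped (13139 against 9171) and a lower mitochondrial share (0.0816% against 0.860%).

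The lower TSS share of naive cells has 2 explanations that the tables argue against. Fragments from the mostly unmapped material would be rarest in naive cells under 5% unmapped, yet these had a TSS share of 35.4%. Lower depth is argued against by cells with 5000 to 20000 fragments, where the smallest of the 3 differences was 14.3 percentage points. A difference in nuclei preparation or tagmentation cannot be told apart from the exposure to leukemia, since each group has 1 library; transfer into a recipient also separates the groups.

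On days 9, 13 and 17, cells with 1.5 to 3 times the median saturation estimate had a lower median TSS share than cells near the median (within 25% of it), by -2.44, -1.71 and -3.24 percentage points, against -0.34 in naive cells. Droplets with random pairs of the library's smaller cells are argued against as the whole cause: against simulated pairs of any cells under 1.5 times the median whose sum fell in the range, the smallest difference was -1.38. Pairs with a kind of cell that is rare on its own stay open. At day 17 an effect of the estimate itself and one of duplicate removal are also argued against as the whole cause, with differences of -3.07 when cells were sorted by usable read pairs and -1.89 at a matched duplicate share. At days 9 and 13 both stay open, since the smallest differences, -1.504 and -0.83, did not pass their bounds by more than their intervals. At a matched duplicate share, days 9, 13 and 17 lay at -1.81, -0.83 and -1.89, with interval half-widths 0.96, 0.43 and 0.77. The difference in naive cells was -0.57 by the same measure, with a half-width of 0.49. Day 13 was thus not told apart from naive cells at a matched duplicate share. No biological explanation was tested.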
